A study of Mus musculus with 2 samples.

How the data were processed

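H3K27ac, acetylation of lysine 27 on histone H3, marks active promoters and active enhancers. It was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the midbrain of mouse embryos of the B6NCrl strain at embryonic day 11.5. Per the labels, there were 2 biological replicates. Each was a pool of midbrains from male and female embryos, 109 embryos in replicate 1 and 88 in replicate 2, and library fragments were in the range of 300 to 500 bp. Both replicates belong to a single group, so no comparison between conditions was possible.

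What was used are 4 peak lists deposited by the authors on the mm10 assembly: a list for each replicate, a pooled list, and a list named as replicated peaks. Per the text files deposited with each sample, each replicate's list derived from that replicate's filtered alignment and control alignments, the pooled list from both replicates' alignments and controls, and the replicated list from the pooled list together with both replicates' lists. The aligner, the peak caller, its settings, and the rule by which replicated peaks were chosen are not given in the sources used here. For each peak the authors deposited a fold enrichment of the ChIP over its control as a linear ratio, the −log10 of a p-value, the −log10 of a q-value, and the distance from the peak's start to its summit. The lists include weak peaks: the lowest deposited −log10 p was 2.01 in replicate 1 and 2.05 in the replicated list, and the share of peaks with a deposited q-value under 0.05 was 76.5% in replicate 1, 87.8% in replicate 2, 81.3% in the pooled list and 95.0% in the replicated list. Fold is the authors' own value and was used to describe, rank or filter peaks within its own list, and once to compare the promoter peaks of X-linked and autosomal genes within the replicated list. Among the alternatives, the promoter fold of named genes was also set beside its value in the other lists. The files hold no read numbers, so sequencing depth is unknown, and a difference in depth between the replicates would change how many weak peaks each list holds.

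Coordinates are given on mm10, counted from 1. Annotation was GENCODE release vM21 and sequence was GRCm38.p6, the same assembly as mm10. This was checked: of the peaks on assembled chromosomes, 28326 of 28326 in the replicated list lay inside the reference chromosome of the same name, as did those of the other lists. Analyses of genes were limited to the 21938 protein-coding genes on the autosomes, X and Y, with 93459 annotated transcription start sites (TSSs).

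Intervals were compared by an overlap of at least 1 bp, and overlap by chance was measured by 100 random circular shifts of a list within each chromosome after runs of undetermined bases had been taken out. A peak was placed at a promoter when its summit lay within 1 kb of a coding TSS, and otherwise in an exon, an intron or between genes. A gene had a promoter peak when a replicated peak overlapped the 1 kb on either side of any of its TSSs. A distal peak, with its summit over 1 kb from every coding TSS, was assigned to the gene with the nearest TSS, which is a convention and not a measured link. Shares are given with Wilson 95% intervals, which cover counting error only and treat neighbouring peaks as independent.

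Before the data were examined, 24 gene lists, 17 sequence motifs, the tests, the alternative settings and the rule for named genes were fixed. Promoter peaks of each list were compared with those of all other coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. Distal peaks per gene were compared with 10000 random lists of the same size, matched on the length of the genome nearer to the gene's TSSs than to any other, in a two-sided permutation test adjusted in the same way. The smallest unadjusted p these permutations can give is 0.0002. The tests of gene lists treat genes as independent. Their p-values may be too small where listed genes are neighbours, as Hox genes are and olfactory receptors may be. Of 1604 listed symbols 1603 were found in the annotation, and the missing symbol was in the erythroid list. Distal peaks within 12.5 kb of each other were stitched into clusters. Motif matches within 200 bp of distal summits were compared by Fisher's exact test, two-sided, with windows of the same width drawn within 100 kb of a distal peak, outside all 4 lists, over 1 kb from coding TSSs and matched on GC content in steps of 2 percentage points. The distance from coding TSSs was added to the design so that controls resembled distal peaks. Of 16521 distal windows 16228 found a control. RFX and HNF1 sites allowed 1 mismatch.

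Named genes were 29 markers fixed in advance, up to 4 members of each list with the highest promoter fold and up to 2 without a promoter peak in alphabetical order, the 10 genes with the most distal peaks, the 10 peaks of highest fold, the genes nearest to the 10 largest clusters, and the 3 tallest peaks found in each replicate alone.

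The alternatives were other overlap, promoter, stitching and window distances, stricter thresholds on the peaks, the pooled list, each replicate's own list alone, TSSs at the 5' end of genes only, random lists matched on promoter CpG content, random lists not matched on domain length, bases covered within 50 kb of the TSS, and control windows not matched on GC. Bases within 50 kb include those of promoter peaks. The replicate overlap, the tests of gene lists against other genes or domain-matched lists, and the motif comparison were tested on simulated data. A known peak overlap of 60% was recovered as 60%. For promoter peaks over 21938 genes, 94% of simulated lists raised to about 86% of 20 members were called and 1.05% of unchanged lists. For distal peaks over the same 21938 genes, the test called 4% of lists raised 2-fold, 34% of lists raised 4-fold, 64% of lists raised 8-fold and 0.19% of unchanged lists, so a list not called may still differ severalfold. These lists were of random genes, and only 4844 of the 21938 genes had a distal peak. Genes without a distal peak stayed without one when raised. Lists whose members mostly have distal peaks were not simulated. Over 5000 simulated windows, an inserted motif with a true log2 odds ratio of 1.12 was recovered at 1.06. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.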

Results

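The data are lists of H3K27ac peaks from the mouse midbrain at embryonic day 11.5, when midbrain neurons are being born from a proliferating neuroepithelium. They came from 1 group of 2 biological replicates, of 109 and 88 pooled embryos. Replicate 1 had 52608 peaks covering 22.9 Mb with a median length of 266 bp, and replicate 2 had 56094 peaks covering 28.6 Mb with a median length of 295 bp. The pooled list had 39990 peaks covering 24.2 Mb and the replicated list had 28329 covering 21.4 Mb, with a median length of 513 bp and a median fold of 4.50. Read numbers are not in the files used here, so the depth of each library is unknown. Unless stated otherwise, genes and regions are described with the replicated list, and fold is the value the authors gave to the peak.

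The first question was how far the replicates shared their peaks. Tall peaks at neural regulators were found in both: the peak over the Sox2 promoter (chromosome 3, 34649902 to 34652113) had a fold of 32.4 in replicate 1 and 46.3 in replicate 2, and the peak over Otx2 (chromosome 14, 48664414 to 48675124) had a fold of 21.8 and 28.9. Of the 52608 peaks of replicate 1, 30399 overlapped a peak of replicate 2, a share of 57.8% (95% interval 57.4 to 58.2). Of the 56094 peaks of replicate 2, 27211 overlapped a peak of replicate 1, a share of 48.5% (48.1 to 48.9). Random circular shifts gave means of 2.03% and 1.89%. The Jaccard index of covered bases was 0.439, against 0.00541 for shifted lists.

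Sharing was nearly complete among tall peaks. In the highest decile of fold, 100% of replicate 1 peaks and 99.9% of replicate 2 peaks overlapped the other replicate, and in the lowest decile 36.6% and 18.3% did. The shares of replicate 1 were uneven among its lower deciles, with 26.9% in the second and 38.2% in the third. Limiting both lists to peaks with a −log10 p of at least 5 raised the shares to 78.7% and 55.0%.

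**Figure D1:**
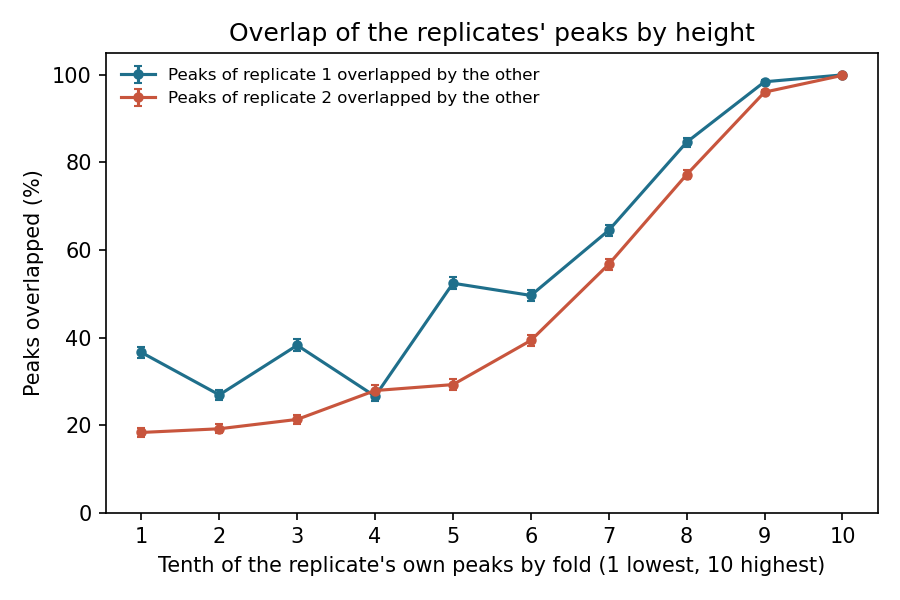
Share of each replicate's peaks that overlapped a peak of the other replicate (y axis, percent) by decile of the peak's fold in its own list (x axis), with Wilson 95% intervals. The shares reached 100% for replicate 1 and 99.9% for replicate 2 in the highest decile.

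The replicated list was a subset of the pooled list: 28329 of 28329 replicated peaks had the start and end of a pooled peak, and 70.8% (70.4 to 71.3) of pooled peaks were kept. Kept peaks had a median fold of 4.50 and a median length of 513 bp, against 3.02 and 218 bp for those not kept. Of the replicated peaks, 91.5% overlapped a peak of replicate 1, 98.0% a peak of replicate 2, and 89.6% (89.2 to 89.9) both. The list therefore held peaks absent from 1 of the replicates' own lists, such as those over the promoters of Twist1, Prdm12, Foxa3 and Afp, which had no peak in replicate 1. It also left out 536 pooled peaks that overlapped both.

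H3K27ac lies at active promoters and at active enhancers, and the peaks fell both near coding TSSs and away from them. Peaks away from coding TSSs include some at promoters of noncoding genes, and enhancer activity was not measured. Of 28326 replicated peaks on assembled chromosomes, 11803 had their summit within 1 kb of a coding TSS, which is 41.7% (41.1 to 42.2) against 3.70% of genome bases and a mean of 4.07% in circular shifts. Introns held 32.8% of peaks and 39.2% of bases, intergenic sequence 21.1% of peaks and 53.4% of bases, and exons 4.47% of peaks and 3.79% of bases. Promoter peaks had a median fold of 5.87 and a median length of 594 bp. The 16523 distal peaks had a median fold of 4.04 and a median length of 459 bp, and lay at a median of 23.4 kb from the nearest coding TSS. Among peaks at or above the median fold, the promoter share was 56.5%.

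Of 21938 coding genes, 9435 (43%) had a promoter peak, with a median fold of 7.41. The share followed promoter CpG content, from 3.37% in the lowest decile of the CpG ratio to 88.0% in the highest. A total of 4844 genes were nearest to at least 1 distal peak, and 3116 genes had both kinds of peak. Of the 86 named genes with a promoter peak, 72 kept one at the gene's 5' end. Afp, Bdnf, Ddc, Dlg4, Egfl7, Fli1, Gata3, Lmx1b, Nav2, Nfe2, Pax6, Rapgef5, Six3 and Tfap2a had theirs near other annotated TSSs alone. The highest promoter peaks of Gse1, Lhx2, Nr2f2, Ptch1, Slc17a6 and Tal1 also lay over 1 kb from the 5' end.

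Genes that pattern the midbrain and the isthmus, the signalling centre between midbrain and hindbrain, carried promoter peaks in 18 of 23 cases (78.3%, exact adjusted p = 0.00228). Otx2, which specifies forebrain and midbrain, had a fold of 25.3 in a peak of 10711 bp. Irx3 had a fold of 40.1 (chromosome 8, 91798852 to 91802054) and Mab21l2, a tectum gene lying inside Lrba, a fold of 20.7. Pax3, expressed in the dorsal midbrain, had a fold of 18.5. The engrailed genes, which mark midbrain and anterior hindbrain, had folds of 9.25 at En1 and 14.9 at En2, and values of 8.55 and 9.90 for En1 and of 15.4 and 16.1 for En2 in the separate replicates. Pax5 had a fold of 4.75 in a peak 859 bp from its TSS, so it was lost with promoters of 500 bp. Pax2, Wnt1, Fgf8 and Gbx2, which are expressed in narrow bands at or near the isthmus, had no promoter peak, although 1, 3, 1 and 1 distal peaks were nearest to them. Other members of the list, such as Fgf17 and Fgf18, had a promoter peak, and breadth of expression was not measured. Gbx2 had a promoter peak in replicate 2's own list (fold 2.62). Against random lists of the same promoter CpG content, which averaged 60.3%, the midbrain and isthmus list was not called (permutation test, adjusted p = 0.109).

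The floor plate and dopaminergic list, whose cells occupy the ventral midline, had promoter peaks at 9 of 19 genes (47.4%, exact adjusted p = 0.818). Lmx1a had a fold of 4.24, Lmx1b a fold of 4.50 in a peak 190 bp from an internal TSS and 8418 bp from the gene's 5' end, Foxa2 a fold of 3.59 and Nr4a2 a fold of 5.72. Shh, the floor plate signal, had a fold of 5.82, and Wnt5a a fold of 14.2. Ddc had a fold of 12.53 in a peak that covered an internal TSS and lay 74575 bp from its 5' end. Th, the rate-limiting enzyme of dopamine synthesis, had no promoter peak and 3 distal peaks, and Aldh1a1 and Arx had no promoter peak. Th had a promoter peak in replicate 1's own list (fold 2.22).

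Regulators of other midbrain neurons had promoter peaks at 16 of 20 genes (80%, exact adjusted p = 0.00228). The GABAergic regulators Tal2, Gata2 and Gata3 had folds of 9.53, 5.01 and 6.02, the last of them at an internal TSS. Nkx6-1 had a fold of 7.80, and the tectal and red nucleus genes Tfap2d and Pou4f1 both had 7.60. Isl1 and Phox2a, of the oculomotor lineage, had no promoter peak, although Isl1 had one in replicate 1's own list (fold 3.04). The call was lost with peaks at or above the median fold (exact adjusted p = 0.0700), with the gene's 5' end only (0.0799) and against lists of matched CpG content (0.129).

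Neural progenitor genes had a promoter peak in 23 of 23 cases (adjusted p = 2.2e-08), and matched lists averaged 62.0% (permutation test, adjusted p = 0.0008, from the smallest p the permutations can give, 0.0002). The highest folds of the list were 45.6 at Pou3f2, 45.4 at Msi1, 42.4 at Sox2 and 29.8 at Pou3f3. The Msi1 peak was also the longest in the replicated list, at 12871 bp. Pax6 had a fold of 5.16 at an internal TSS. Proneural and early neuron genes, which drive and mark exit from the progenitor state, had a promoter peak in 22 of 24 cases (91.7%, adjusted p = 3.94e-06), against 45.9% in matched lists (permutation test, adjusted p = 0.0008). Ascl1 had a fold of 20.3, Myt1 of 19.7, Myt1l of 16.9, Insm1 of 16.3, Tubb3 of 12.48 and Neurog2 of 9.10. Atoh1 and Neurod4 had no promoter peak. Both lists kept their calls under every alternative.

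Genes of mature synapses had promoter peaks in 6 of 20 cases (30%, exact adjusted p = 0.292). Dlg4 (17.4, at an internal TSS), Bdnf (9.98, near an internal TSS), Slc17a6 (8.99) and Camk2a (5.0) had the highest folds, and Arc and Gabra1 had none. Glial genes, expressed mostly after neurogenesis, had a lower share, at 2 of 18 genes (11.1%, exact adjusted p = 0.00991). The pair was Slc1a2, with a fold of 14.2, and Slc1a3, with 3.07, and both glutamate transporters are also expressed in radial progenitors. The glial call was lost with the pooled list (exact adjusted p = 0.195), with replicate 2's list (0.300), with replicate 1's list (0.676) and against lists of matched CpG content (0.0790). The share was 27.8% with the pooled list, 33.3% with replicate 2's list and 38.9% with replicate 1's list.

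Genes of neighbouring regions of the neural tube had lower shares. Hox genes, which pattern the hindbrain and spinal cord, had a promoter peak in 0 of 39 cases (adjusted p = 3.23e-09), while lists of matched CpG content averaged 57.4% (permutation test, adjusted p = 0.0008). Hoxa2 and Hoxb1 had no distal peak either. Because Hox genes lie in clusters and both tests treat genes as independent, the Hox p-values may be too small. Forebrain genes had promoter peaks in 4 of 21 cases (19%, adjusted p = 0.0350), against 52.6% in matched lists (permutation test, adjusted p = 0.00373). These were Lhx2 (6.96, at an internal TSS), Six3 (5.48), Nkx2-1 (4.04) and Emx2 (3.57), while Foxg1, Dlx1 and Dlx2 had none. Dlx1 had a promoter peak in replicate 2's own list (fold 4.67) and Dlx2 in replicate 1's (4.01). Other hindbrain and spinal cord genes had promoter peaks in 3 of 19 cases (15.8%, adjusted p = 0.0251), against 55.8% in matched lists (permutation test, adjusted p = 0.0018): Dbx1 (10.1), Mafb (9.58) and Prdm12 (4.29). The forebrain call was lost with the pooled list (exact adjusted p = 0.331), with either replicate's own list (47.6%, adjusted p = 1) and with promoters of 500 bp (0.0557) or 2.5 kb (0.214). The hindbrain call was lost with the pooled list (exact adjusted p = 0.141), replicate 2's list (0.0952) and replicate 1's list (0.0587), where the shares were 26.3%, 26.3% and 21.1%.

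Genes of other tissues were mostly without promoter peaks. Epithelial genes had 0 of 15 (exact adjusted p = 0.000908), germ cell and pluripotency genes 0 of 14 (0.00140) and olfactory receptors 0 of 1135 (1.65e-286), and these kept their calls under every alternative. Heart and muscle genes had 1 of 18 (5.56%, exact adjusted p = 0.00228), which was Myh7 with a fold of 12.6. Liver and endoderm genes had 2 of 18 (11.1%, exact adjusted p = 0.00991), with Foxa3 at 4.83 in a peak beside TSSs of Sympk and Afp at 3.24 in a peak 16710 bp from its 5' end. Macrophage genes had 1 of 15 (6.67%, exact adjusted p = 0.00572), which was Cd68 at 3.07. Endothelial genes had 2 of 18 (11.1%, exact adjusted p = 0.00991), Fli1 at 5.23 and Egfl7 at 3.45, and Cdh5 had none.

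Erythroid genes had 3 of 16 (18.8%, exact adjusted p = 0.0846), namely Tal1 (7.01), Slc4a1 (3.31) and Nfe2 (3.20), and Tal1 also belongs to the list of other midbrain neuron regulators. Hba-a1, Alb and Myh6 had no promoter or distal peak. Mesenchyme and neural crest genes had 6 of 25 (24%, exact adjusted p = 0.0816), led by Tfap2a (6.02), Foxc1 (5.23), Alx4 (4.63) and Tfap2b (4.24). With peaks at or above the median fold the erythroid list (exact adjusted p = 0.0230) and the mesenchyme list (0.0241) were called lower, and the erythroid list also with the gene's 5' end only (0.0472). The erythroid share was 31.2% with the pooled list, 43.8% with replicate 2's list and 25% with replicate 1's list, and was not called with these. The macrophage and endothelial calls were lost with the pooled list (exact adjusted p = 0.0650 and 0.0836) and with each replicate's own list (exact adjusted p = 0.0562 and 0.300 with replicate 2's, 0.0938 and 0.0851 with replicate 1's). The macrophage share was 20% with each of these lists, and the endothelial share was 22.2% with the pooled list, 33.3% with replicate 2's list and 22.2% with replicate 1's list. The liver share was 16.7% with replicate 2's list and 0% with replicate 1's list, and the heart share 11.1% with replicate 1's list, and these stayed called lower. Against matched CpG content, the liver (permutation adjusted p = 0.325), heart (0.0528) and macrophage (0.887) calls were lost and the endothelial call was kept (0.0408).

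Housekeeping genes set a reference for promoters active in every cell. Ribosomal protein genes had a promoter peak in 30 of 30 cases (exact adjusted p = 1.19e-10), with folds of 26.5 at Rpl7, in a peak shared with Rdh10, 15.9 at Rpl19, 14.9 at Rpl10a and 13.7 at Rpl13. Cell cycle genes, active in the dividing neuroepithelium, had 18 of 21 (85.7%, exact adjusted p = 0.000309), led by Mcm7 (15.3, beside Ap4m1), Aurkb (12.2), E2f1 (10.8) and Plk1 (8.19). Bub1 and Ccnb1 had none in the replicated list, but each had one in replicate 2's own list (folds 3.07 and 5.52). With replicate 2's list the cell cycle share was 21 of 21 (100%).

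Among signalling pathways, Fgf genes had 16 of 19 (84.2%, exact adjusted p = 0.000908) and Hedgehog genes 11 of 13 (84.6%, adjusted p = 0.00572). Wnt genes had 11 of 21 (52.4%, exact adjusted p = 0.405). Axin2, a target of Wnt signalling, had a fold of 42.8, Ptch1, the Hedgehog receptor and target, 35.5, and Spry2 and Spred1, inhibitors of Fgf signalling, both 27.2. Tcf7l2 had a fold of 22.4, Gas1 of 28.1, Gli3 of 23.6 and Dusp6 of 16.5. The value of 30.3 listed for Fgfr2 came from a peak at the TSS of Ctbp2, which an Fgfr2 read-through transcript shares in the annotation. Dkk1, Lgr5, Hhip, Disp1, Etv4 and Etv5 had no promoter peak in the replicated list. Lgr5 had one in each replicate's own list (folds 3.15 and 4.19). Disp1 (4.16), Etv4 (3.06) and Etv5 (4.19) had one in replicate 2's own list. Against matched CpG content, the cell cycle (permutation adjusted p = 0.313), Hedgehog (0.129) and Fgf (0.109) calls were lost and the ribosomal call was kept (0.0008).

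**Figure D2:**
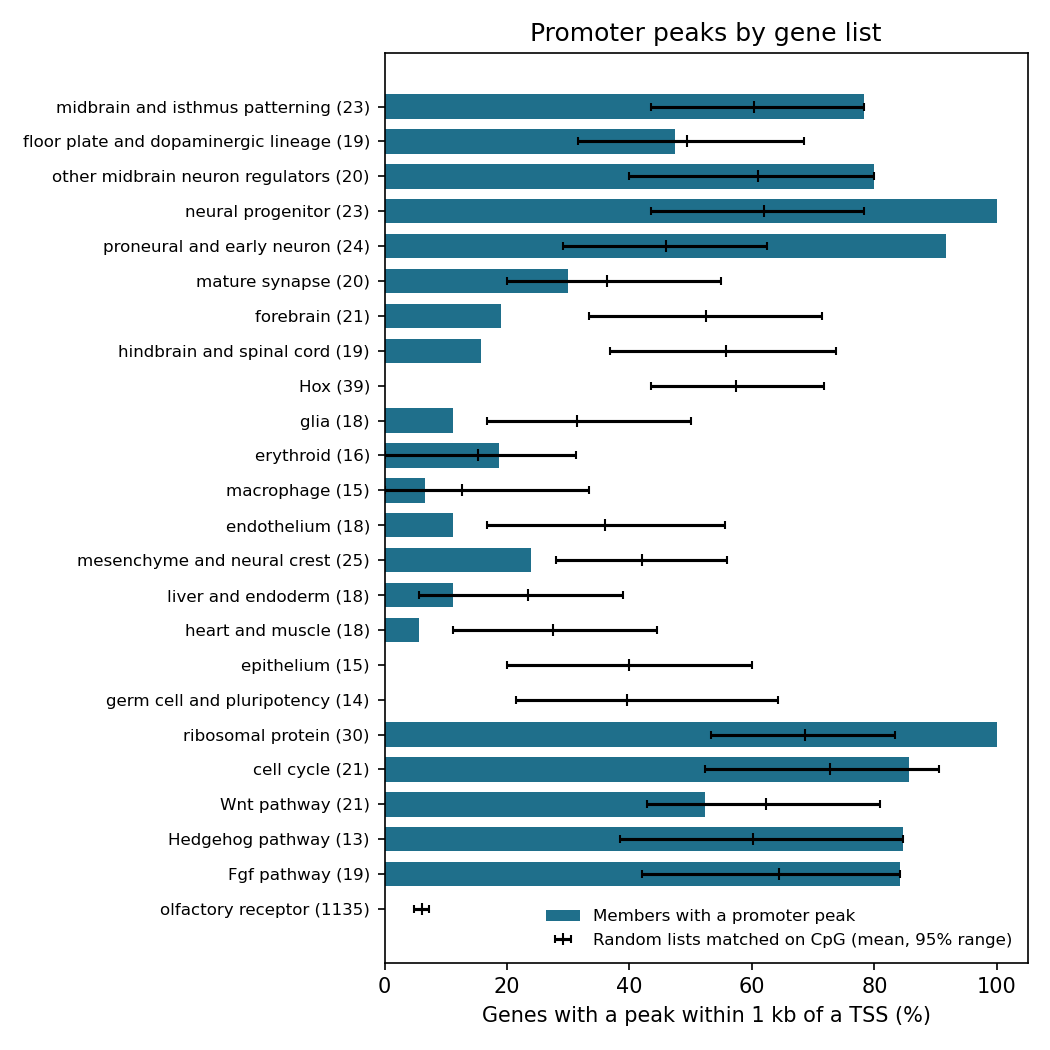
Share of genes with a promoter peak (x axis, percent) in each of the 24 gene lists (y axis). Neural progenitor and ribosomal protein genes reached 100%, and Hox, epithelial, germ cell and olfactory receptor genes 0%.

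Distal peaks were more numerous than in matched random lists near genes of 3 neural lists. Neural progenitor genes had a mean of 9.52 distal peaks per gene, against 1.47 (95% range 0.391 to 3.48) for random lists matched on domain length (permutation test, adjusted p = 0.0016). Sox2 alone had 40, Pou3f3 had 33, and Pou3f2 had 18. Midbrain and isthmus genes had a mean of 8.30 (SD 7.39 between 23 genes) against 1.60 (0.478 to 3.57; permutation test, adjusted p = 0.0016), with 25 at Pax3, 19 at Irx3, 18 at Otx2, 17 at En1 and 11 at En2. Proneural genes had 7.17 against 1.62 (0.458 to 3.71; permutation test, adjusted p = 0.0024), with 25 at Myt1l, 11 at Ascl1 and 8 at Neurog2. These calls were kept under every alternative, of which the bases covered within 50 kb also count promoter peaks. The means followed the number of peaks in the list. They were 17.5, 16.6 and 14.0 with replicate 2's list, 15.5, 13.0 and 12.04 with replicate 1's list, and 4.70, 3.39 and 3.21 with peaks at or above the median fold.

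Hedgehog genes had a mean of 6.69 against 1.70 and Wnt genes 4.43 against 1.41 (permutation test, adjusted p = 0.0456 for both), with 18 distal peaks each at Ptch1, Gli3 and Axin2 and 27 at Tcf7l2. Both calls were lost with peaks at or above the median fold (permutation adjusted p = 0.0552) and with a distal distance of 2.5 kb (0.0736 and 0.0682), and the Wnt call without replicate 2 (0.0568). The Hedgehog and Wnt means were 13.3 and 9.52 with replicate 2's list and 12.4 and 7.76 with replicate 1's list. Olfactory receptors had fewer, 0.0106 per gene against 0.213 (permutation test, adjusted p = 0.0016).

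The other lists were not called in the permutation test. Regulators of other midbrain neurons had a mean of 4.20 (permutation adjusted p = 0.134), the floor plate list 3.68 (0.162), with 15 at Foxa2 and 18 at Ddc, and Fgf genes 2.95 (0.266). Forebrain genes had 1.43 (0.619), glial genes 1.22 (0.619), macrophage genes 1.33 (0.325), hindbrain genes 0.947 (0.944) and mature synapse genes 0.9 (0.834). Cell cycle genes had 0.952 (0.266), ribosomal genes 0.700 (0.137), mesenchyme genes 0.640 (0.325), endothelial genes 0.611 (0.619), epithelial genes 0.533 (1), liver genes 0.333 (0.665), germ cell genes 0.286 (0.619), erythroid genes 0.188 (1), heart genes 0.167 (0.173) and Hox genes 0 (0.137). Without matching on domain length, other midbrain neuron regulators (permutation adjusted p = 0.0132), the floor plate list (0.0187) and Fgf genes (0.0427) were called higher. Hox genes were then called lower (0.00096). By bases within 50 kb, which include promoter peaks, these lists were called in the same directions. On simulated lists of 20 random genes, most of them without a distal peak, the matched test called 34% of those raised 4-fold. It could therefore miss differences of that size.

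**Figure D3:**
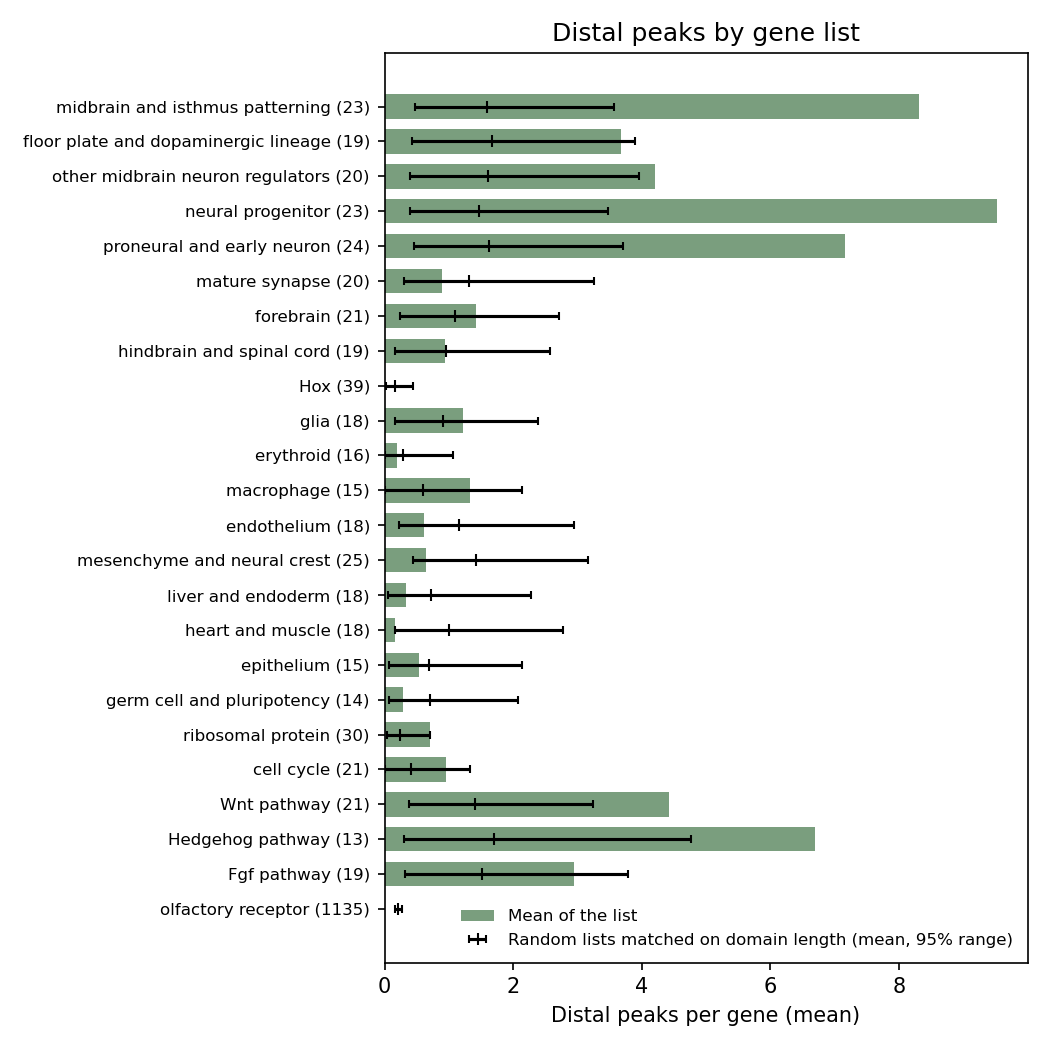
Mean number of distal peaks per gene (x axis) in each gene list (y axis), beside the mean and 95% range of random lists matched on domain length. Neural progenitor (9.52), midbrain and isthmus (8.30) and proneural (7.17) genes lay above their ranges.

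Over the whole genome, the genes with the most distal peaks were Gse1 with 88 and Msi2, an RNA-binding protein of neural progenitors, with 86. Rapgef5 had 63, Zfp608 had 55, Zmiz1 had 50, Zfp423 had 44 and Nav2 had 42. Nr2f2 had 41, as did Ccdc182, which lies beside Msi2, and Gm11146, at the Mir99ahg locus. Each replicate's own, longer list gave these genes higher counts and partly another order. Gse1 had 148 in replicate 1 and 153 in replicate 2, Msi2 had 125 and 156, Rapgef5 had 110 and 100, Zfp608 had 92 and 126, and Zmiz1 had 103 and 109.

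The tallest peak (chromosome 5, 123135564 to 123142802) had a fold of 58.0, 48.7 in replicate 1 and 65.1 in replicate 2, and covered TSSs of Setd1b and of the noncoding gene AI480526. The next (chromosome 5, 115489611 to 115490353, fold 56.5) was only 743 bp long and covered the TSS of the small nuclear RNA gene Gm24407, with that of Gm24265 outside the peak but within 1 kb. Both belong to a gene family with repeated copies. Next came promoters of Sp3 (54.9), of Zc3h6 (51.2), of Nr2f1 (50.2), a regulator of neural patterning, of the chromatin protein Brd2 (50.2) and of Kmt5b (48.2). A peak covering TSSs of Mllt10 and 1810059C17Rik had a fold of 53.5, and 1 at Gm11523 a fold of 50.1. The peak at Mir124-2hg (chromosome 3, 17784631 to 17792300), the host of a neuronal microRNA, had a fold of 48.3, with 19.4 in replicate 1 and 58.2 in replicate 2.

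Distal peaks stitched within a set distance formed 8602 clusters, of which 3556 held 2 or more peaks, ranked by covered bases; replicate 2's list gave 16996 and replicate 1's list 18874. The largest lay at Msi2 (chromosome 11, 88394800 to 88605719), with 67 peaks covering 59941 bp at a mean fold of 5.19; the largest cluster covered 109187 bp with replicate 2's list and 83177 bp with replicate 1's. Clusters at Gse1 held 46 peaks over 48379 bp (chromosome 8, 120396952 to 120565989) and 30 peaks over 30644 bp. A cluster nearest to Cstad (chromosome 2, 30639203 to 30726597) covered 40741 bp and 1 nearest to Polg (chromosome 7, 79496280 to 79550410), with Mir9-3hg inside it, covered 35764 bp. Clusters at Igdcc3 (34286 bp), Nr2f2 (32649 bp), Nr2f1 (26103 bp), Sox2 (26014 bp) and Cdk5rap3 (25687 bp) completed the first 10. Of these 10, 8 overlapped the first 10 with the pooled list, 7 without replicate 1, 8 without replicate 2 and 7 with stitching within 5 kb.

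Sequence near distal summits was compared for 17 binding sites. They included sites of factor families active in neural tissue and of others, such as GATA, MEF2, HNF1, ETS and CTCF. The summits are those of a histone mark, and binding of the factors was not measured. Homeodomain sites (TAATTA) lay in 8.61% of 16228 peaks and 6.08% of as many windows matched on GC content, a log2 odds ratio of 0.54 (95% interval 0.42 to 0.67, exact adjusted p = 1.59e-17). POU sites (ATGCAAAT), bound by factors such as Pou3f2, lay in 3.01% and 1.76%, a log2 odds ratio of 0.79 (0.58 to 1.00, exact adjusted p = 6.47e-13). CAGCTG, a site of proneural bHLH factors, lay in 29.6% and 23.3% (0.46, exact adjusted p = 8.89e-36), SOX sites (ACAATG) in 21.3% and 17.9% (0.31, adjusted p = 2.37e-13) and forkhead sites (TGTTTAC) in 5.70% and 4.44% (0.38, adjusted p = 8.03e-07). CAGATG, the other bHLH site tested, lay in 31.5% and 30.6% (0.06) and was not called. AP-1 sites were less frequent, in 6.12% and 7.15% (−0.24, exact adjusted p = 0.000601). The other 11 motifs were not called: MEF2 (exact adjusted p = 0.121), RFX (0.131), CAGATG (0.172), TEAD and LEF/TCF (0.186), ETS (0.314), OTX and CTCF (0.353), and GATA, NFI and HNF1 (1).

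Against windows 5 kb away that were not matched on GC content (44.9% against 50% in peaks), the homeodomain value turned to −0.44 (exact adjusted p = 5.72e-14), and the SOX (0.00, adjusted p = 0.920) and forkhead (0.09, adjusted p = 0.268) calls were lost. The POU call was lost within 100 bp of the summit (0.37, exact adjusted p = 0.0609). CAGCTG stayed higher and AP-1 lower under every alternative, although base composition beyond GC content was not tested for AP-1. OTX sites were called lower within 100 bp (−0.35, exact adjusted p = 9.74e-07), against windows 5 kb away (−0.34, 1.91e-11), without replicate 1 (−0.066, 0.0471) and without replicate 2 (−0.15, 6.34e-06). RFX and TEAD sites were called higher against windows 5 kb away (0.30 and 0.095), without replicate 1 (0.23 and 0.098) and without replicate 2 (0.16 and 0.067). MEF2 sites were called higher within 100 bp (0.99) and without replicate 1 (0.48), and lower against windows 5 kb away (−0.55). CTCF sites were called lower within 100 bp (−1.31). Against windows 5 kb away GATA sites were called lower (−0.33), and CAGATG (0.12) and ETS (1.44) sites higher.

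**Figure D4:**
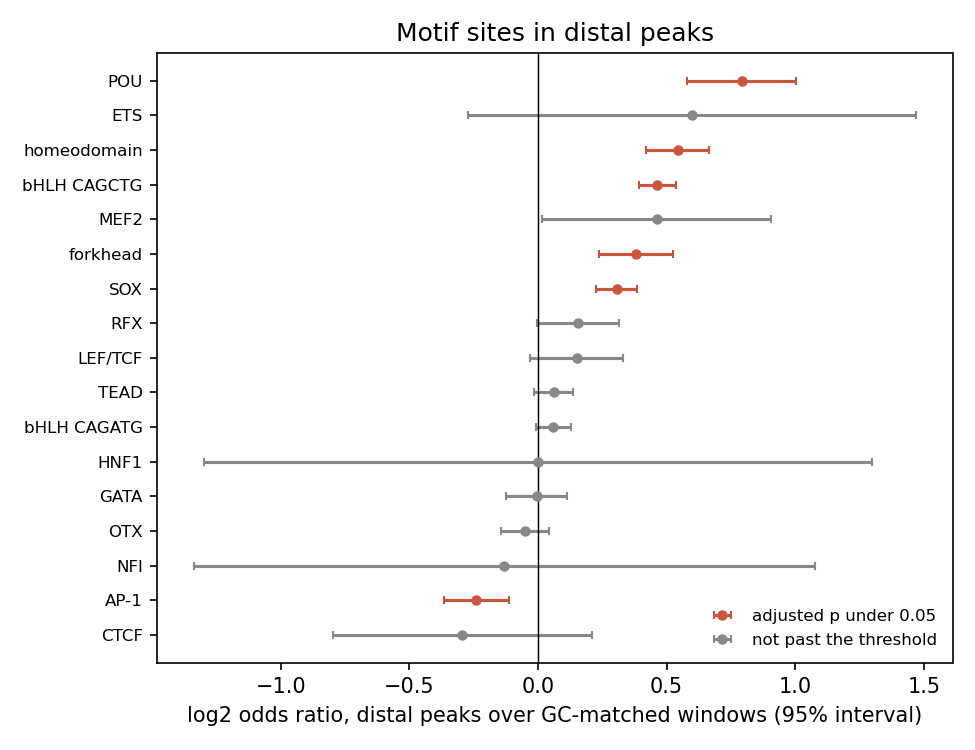
Log2 odds ratio of each motif in distal peaks against GC-matched windows (x axis), with 95% intervals, for 17 motifs (y axis). POU (0.79), homeodomain (0.54) and CAGCTG (0.46) had the highest called values and AP-1 (−0.24) was below 0.

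Peaks found in 1 replicate alone were low. The 22209 peaks of replicate 1 without a partner had a median fold of 3.08, against 4.01 for its shared peaks, and 11.2% (10.8 to 11.6) lay at promoters, against 41.4% of shared peaks. The 28883 of replicate 2 had a median fold of 3.43, against 5.52, and 18.0% (17.6 to 18.4) lay at promoters, against 42.0%. The tallest peak of replicate 2 without a partner lay 8 bp from a TSS of Kctd9 (chromosome 14, 67716097 to 67716704, fold 13.9), followed by peaks at Trmt13 and Syt11 (both 10.6). In replicate 1 the tallest lay 147 bp from a TSS of Ttc25 (chromosome 11, 100545259 to 100545644, fold 6.47), followed by distal peaks nearest to Cachd1 (6.31) and Gm11146 (6.16).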

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

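The test by list length was chosen only after its result was partly seen, and the number of shuffled sites in the motif test was raised after a first result had been seen.

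A few peaks lay on unplaced sequences, which the comparisons by location, gene, cluster and motif do not use, although the overlaps between lists count them: 4 in the pooled list, 8 in replicate 1 and 6 in replicate 2. The tallest, on the sequence GL456216 assigned to chromosome 4, had a fold of 36.5 in the pooled list, 25.9 in replicate 1 and 42.5 in replicate 2, so it was found in both libraries. The others had folds under 5. Read placement on these sequences was not analysed here.

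Peaks found in replicate 2 alone lay at promoters more often (18.0%) than those of replicate 1 alone (11.2%). A preference of the libraries for GC-rich DNA should also appear away from promoters, where the mean GC content differed by 0.648 percentage points (95% interval 0.536 to 0.767), under the bound of 1 set in advance; at promoters it was 56.0% and 53.9%, so a preference limited to the highest GC content remains possible. The length of the lists was also argued against: with the 20000 peaks of smallest p from each, the shares still differed by 10.1 points (8.24 to 11.9). A difference in depth or in enrichment remains open, since the files give no read numbers. No biological explanation was tested, since the design has 1 group.

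Homeodomain, POU, CAGCTG, SOX and forkhead sites were more frequent in distal peaks than in GC-matched windows, and base composition beyond GC content may explain part of this. Shuffled versions of each site, with the same bases and number of CpG, reached as high a log2 odds ratio in 0% of 13 for homeodomain, 1.5% of 200 for POU and 4.88% of 41 for CAGCTG, each at or under the bound of 5% set in advance. The CAGCTG value lay near that bound. Only 13 shuffled homeodomain sites exist, too few to resolve a bound of 5%, so composition remains open for homeodomain sites. The highest log2 odds ratio of these 13 was 0.47, against 0.54 for the real site. For SOX, 10.1% of 99 shuffled sites and for forkhead 14.0% of 179 did, so composition remains open for them. AP-1 and OTX sites were not shuffled, so composition remains open for their lower values too. The lowest shuffled version of each tested site ranged from −0.40 for SOX to −1.11 for POU, beyond the −0.24 of AP-1. No biological explanation was tested, since the design has 1 group.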

How the results depend on the processing

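No alternative here was chosen after the data were seen, and all of them were run. No paired analysis was possible because the design has 1 group. Where values moved, the cause was not tested unless a stricter or longer list of peaks, or a wider distance, gives it by construction.

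Replicate overlap moved with the threshold and the rule. With a −log10 p of at least 5 it was 78.7% and 55.0%, with a Jaccard index of 0.526, and 17.9% and 25.5% of replicate-only peaks lay at promoters. With 50% of the peak covered it was 51.4% and 37.9%, with 28.4% and 10.4% in the lowest deciles and 97.9% in the highest of replicate 2; replicated peaks then overlapped replicate 1 in 85.2%, replicate 2 in 95.6% and both in 81.0%, and 13.1% and 19.7% of replicate-only peaks lay at promoters. Among the top 30000 by fold it was 67.6% and 60.01%, with a Jaccard index of 0.521, and ranked by p the lowest deciles were at 31.8% and 17.1%. Replicate 2-only peaks kept the higher promoter share at the stricter p and with 50% covered.

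The promoter share of peaks was 36.7% at 500 bp, 47.2% at 2.5 kb, 43.4% for any part of the peak, 35.7% for the pooled list and 56.5% at or above the median fold, and without either replicate 28.7% to 29.6%.

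Of the gene-list results for promoter peaks under alternatives, 156 kept direction and call, 27 lost the call, 3 gained it and 6 reversed. Matched CpG content gave 3 lists higher and 7 lower, the pooled list 6 lower, and each replicate's list 6 lower. The floor plate list turned lower at or above the median fold (31.6%), at 5' ends (36.8%) and against matched CpG content (47.4%), where the Wnt list (52.4%) also turned lower and the erythroid list (18.8%) higher; the forebrain list turned higher (47.6%) without replicate 2; none of these turns was called.

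Of the distal results, 142 kept direction and call, 5 lost the call, 12 gained it and 9 reversed. The bases covered within 50 kb count promoter peaks as well. Twist1, for example, had 0 distal peaks and 317 bases, the length of its promoter peak. Calls by bases, such as those gained by ribosomal and cell cycle genes (permutation adjusted p = 0.0264 and 0.0324), therefore do not describe distal peaks alone. Lists called higher numbered 3 at or above the median fold, 3 at 2.5 kb, 8 without matching on domain length and 10 by bases within 50 kb; lists called lower numbered 2 without matching, 3 by bases and 1 to 2 without a replicate. Without matching, mature synapse (0.9), hindbrain (0.947) and ribosomal (0.7) genes turned; by bases, mature synapse (2182 bp) and forebrain (988 bp) genes did; at or above the median fold, forebrain (0.381) and epithelial (0.333) genes did; erythroid and epithelial genes ranged from 0.625 to 0.812 and from 1.33 to 1.67 without a replicate, and turned without replicate 2 alone.

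Of the motif results, 52 kept direction and call, 3 lost the call, 16 gained it and 14 reversed. Motifs called lower numbered 3 at 100 bp and 5 against windows 5 kb away, where homeodomain (−0.44), LEF/TCF (−0.039), MEF2 (−0.55), NFI (1.28) and CTCF (0.25) turned. At or above the median fold, CAGATG (−0.038), NFI (1.14) and GATA (0.16) turned, as did GATA at 100 bp (0.082). Without a replicate, 7 to 8 motifs were higher and 2 lower, with NFI at 0.15 to 0.98, GATA at 0.054 to 0.073 and CTCF at −0.32 to 0.020.

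Clusters numbered 16996 to 18874 without a replicate, where the largest covered 83177 to 109187 bp; it covered 103992 bp with the pooled list and 34286 bp with stitching within 5 kb. The promoter fold of named genes stayed within the spread between replicates in 513 cases and moved in 55. Cases where the peak was lost are not counted. Settings that kept the replicated list reused its folds, as did the pooled list, which holds every replicated peak. Staying there was therefore largely fixed by construction. The spread came from the same replicates' folds, so where the main fold lay between them a replicate's value had to stay as well. The number of distal peaks was followed only for the genes with the most distal peaks. By its ratio to the main count, and not by the spread between replicates, it stayed in 21 cases and moved in 29. Depth was not given, so its effect on weak peaks was not measured.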

Other observations

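The tests of promoter peak length were chosen only after the result was seen, and the microRNA and noncoding genes named here were chosen after the data were seen.

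Several microRNA genes of neurons and neural progenitors had replicated peaks close by, counted here with no test. Within 10 kb of Mir124a-1, Mir124a-2 and Mir124a-3, the neuronal microRNA, lay 7, 5 and 5 replicated peaks covering 13038, 12262 and 8510 bp, with highest folds of 23.3, 48.3 and 25.5. The progenitor microRNA genes Mir9-2 and Mir9-3 had 5 and 10 peaks covering 13557 and 13236 bp with highest folds of 40.5 and 17.4, and Mir9-1 had 2 peaks with a highest fold of 12.3. Mir219a-1 and Mir219a-2, which later act in oligodendrocytes, had 4 and 7 peaks with highest folds of 35.7 and 32.1, and Mir137 had 2 with a highest fold of 6.25. Of the neuronal Mir128 genes, Mir128-1 had 0 peaks and Mir128-2 had 1 of 340 bp with a fold of 2.88. No peak lay within 10 kb of the muscle genes Mir1a-1, Mir133a-1 and Mir206, the liver gene Mir122, the myeloid gene Mir223 or the Hox-cluster genes Mir10a and Mir196b. The blood genes Mir142 and Mir144 each had 2. The long noncoding Sox2ot, which spans Sox2, had 31 peaks, Mir99ahg 43, Mir9-3hg 24 and Rmst 11. Sox2ot (chromosome 3, 34104270 to 34682619) and Mir99ahg (chromosome 16, 77236317 to 77773427) are long, so their counts cover more sequence. Peaks at promoters of nearby coding genes were not set apart in any of these counts.

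Promoter peaks of several neural lists were long, and the height of the peaks was tested as a reason. Against random genes with promoter peaks of the same fold decile, the geometric mean length was 2.31 times that of the random lists for neural progenitor genes (95% range of random lists 0.820 to 1.22), 2.02 for midbrain and isthmus genes, 1.82 for the floor plate list and 1.84 for proneural genes (permutation test, adjusted p = 0.0006 for each). In the same permutation test Fgf genes were at 1.62 (adjusted p = 0.00096), mature synapse genes at 1.61 (0.0180), Hedgehog genes at 1.48 (0.0165), other midbrain neuron regulators at 1.44 (0.0052) and Wnt genes at 1.41 (0.0272). Ribosomal protein genes (0.856, adjusted p = 0.0661), cell cycle genes (0.930, 0.514) and mesenchyme genes (1.42, 0.0658) were not called in the permutation test. Height at the level of fold deciles was therefore argued against as the only reason for the neural progenitor list. Differences of height inside a decile remain open. Pou3f2, Msi1, Sox2 and Pou3f3, with folds of 29.8 to 45.6, were matched to genes from the whole highest decile, so height was not held equal for them. Whether gene length or the way peaks were joined accounts for this was not tested.

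The share of noncoding genes with a promoter peak was counted with no test. Of 5854 lincRNA genes 672 (11.5%) had one, and of the 5134 over 5 kb from a coding TSS 383 (7.46%) did; of 190 bidirectional noncoding genes 137 (72.1%) did, and processed pseudogenes had a share of 0.674%. Bidirectional genes lie at coding promoters, so their share counts the same peaks as those.

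Fewer X-linked genes (242 of 948, 25.5%) than autosomal genes (9193 of 20807, 44.2%) had a promoter peak (Fisher's exact test, two-sided, p = 3.2e-31). Promoter CpG content was argued against as the whole cause, since random autosomal lists of the same CpG content had a mean of 32.8% (30.4% to 35.3%). This lay above the 25.5% of X-linked genes but below the 44.2% of all autosomal genes, so CpG content may account for part of the gap. Weaker peaks on X may be a cause: the median fold of X-linked promoter peaks was 0.844 of the autosomal (95% interval 0.786 to 0.940). The interval met neither bound set in advance, which leaves this open. Genes whose peak was too weak to be called do not enter this ratio. Each replicate pooled male and female embryos, so the sexes could not be set apart. No biological explanation was tested, since the design has 1 group.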
